A study of Brassica napus with 28 samples.

How the data were processed

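PolyA RNA from seeds of Brassica napus was sequenced in 28 libraries, 4 for each of 7 groups set by day temperature (21 or 32 °C), age (14, 18 or 20 days after pollination, DAP) and, for heat-grown seeds at 20 DAP, by whether the seed coat was intact or ruptured. Groups were taken from the sample labels, and samples with the same replicate number in different groups were not treated as pairs. The deposited table holds raw counts per gene for every library, whole numbers with no normalization, per the file headers. The deposited file of each sample holds a signal per gene that equals, within 1% and with identifiers at 2 loci matched locus by locus, the count divided by 1 factor for that sample, and genes at 0 are left out of it. The submitters' processing notes list FastQC, Trimmomatic 0.39, STAR 2.7.3a, Picard 2.25.6, MultiQC 1.10.1, featureCounts 2.0.3 and DESeq2 1.34.0, without the role or order of each. The genome build is not given in the sources used here.

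The count table has 119367 records and 119362 identifiers, of which 5 stand at 2 loci. The identifiers of 87487 records (73.3%) were found in a table of gene names for the assembly Da-Ae, and 484 of them carried a name beyond a locus number. The per-sample files lack 292 genes that have counts, 291 of them non-coding by their transcript identifier, so the count table was used for every result. Strandedness is not stated, so reads from antisense or overlapping genes, and from near-identical copies on the A and C subgenomes, can be counted for either gene. No sample was left out.

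Differences were tested in R 4.3.3 with edgeR 4.0.16 on the raw counts, with the data.table package (version 1.17.8) for reading the files. Genes were kept by filterByExpr with the group factor, libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersions and a term per group was fitted to all 28 libraries. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. There were 11 comparisons fixed in advance, of which 5 were main comparisons: heat against control at each of the 3 ages, ruptured heat-grown against control seeds, and ruptured against intact heat-grown seeds. The other comparisons followed development within each temperature and asked whether the heat effect differed between ages. CPM values use the TMM-adjusted library totals, and log2 CPM uses a prior count of 2. Library totals ran from 41640918 to 63294580 counts. A gene with no count in a group was given a floor of 3 counts per library for a lower bound on its fold, and fitted folds of such genes depend on the prior count.

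The named genes of each main comparison followed a fixed rule. They were the 5 largest rises and 5 largest falls among called genes with a name, a mean of at least 8 CPM over the 8 libraries and no overlap between the 2 groups, with at most 1 gene per identical product name. From the 8 lists with the smallest p, the 2 called members with the largest change in the direction of the list and a mean of at least 1 CPM were added. For the other comparisons 3 rises and 3 falls were taken by the first part of the rule. The criterion of no overlap was not applied to the comparisons of heat effects between ages.

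Of 22 gene lists fixed in advance, 8 had at least 3 tested genes and were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. There were 9 lists with 1 or 2 tested genes, 1 with named genes of which none was tested and 4 with no named gene. The tested lists covered oil, late embryogenesis, maturation regulators, abscisic acid signalling, flavonoids, mucilage and seed coat, lignin and secondary wall, and redox genes. After the names had been seen, 12 families were added by symbol and tested in the same way.

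The position of a library on normal development was the mean log2 CPM of genes that rose in a control comparison minus that of genes that fell. It was compared between groups by a two-sided exact permutation test over the 70 ways to choose 4 of 8 libraries, whose smallest p is 0.0286. Each comparison was also run over the 35 splits of its 8 libraries, and the comparisons of heat effects over 24 random regroupings and the real one, fitting only the groups involved.

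The alternatives planned were RLE and upper-quartile factors, DESeq2 1.42.0, no low-count filter, a filter of 1 CPM in at least 4 libraries, the replicate number as a block, a fit of only the groups compared, thinning to the smallest total, leaving out the 100 most counted genes, a log2 change of at least 1, an estimated correlation for lists, and leaving out each library in turn. For positions they were genes past a log2 change of 1 and leaving out the storage, oil and late embryogenesis lists. Added later were a fit without a pair of libraries in doubt, picked by their values on the third principal component (THT_14DAP replicate 1 and THT_20DAP_SCR replicate 1), leave-one-out fits for lists and shared genes, thinning and the 100 most counted genes for positions, and a comparison of heat-grown seeds at 14 DAP with control seeds at 20 DAP.

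Replicate numbers were checked for pairing between groups. The mean correlation of deviations from the group mean was 0.00119, 0.000332, -0.00290 and 0.00529 for replicates 1 to 4, on average 0.000976 for the same number and -0.000277 for different numbers. For 8 of 28 libraries their own number, out of 4, had the highest mean correlation over the other groups.

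The pipeline was tested on simulated data with 200 changed genes. In the setting of heat at 14 DAP, edgeR recovered 38.8% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold among 60081 tested, and 7 of its 154 calls were unchanged genes. In that of ruptured against intact seeds it recovered 46.3%, 77.6% and 100% among 60058, with 12 unchanged genes in 161 calls. DESeq2, on 61472 genes, recovered 52.2%, 85.1% and 100% with 22 unchanged genes in 180 calls in the first setting, and 50.7%, 89.6% and 100% with 30 in 190 in the second. In both settings camera found the raised list of 15 genes and none of 20 unchanged lists. Simulated counts were drawn independently for each gene, around the same mean in every group apart from the changed genes. The main comparisons called 18.4% to 55.0% of genes, and real lists were often smaller and held correlated genes. The simulation therefore does not test the preset correlation, or the scaling where a large share of genes changes.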

Results

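Seeds of the spring oilseed rape cultivar Topas DH4079 were profiled by polyA RNA sequencing at 14, 18 and 20 days after pollination (DAP). Plants had grown with days at 21 °C (control) or at 32 °C (heat) from the start of bolting. At 20 DAP the heat-grown seeds were sampled as intact seeds and as seeds whose coat had ruptured. The 28 libraries made 7 groups of 4, which the labels describe as 4 biological replicates from 3 plants, without saying how plants and replicates correspond. Every p value here treats the 4 libraries of a group as independent, which the labels do not settle. Library totals ran from 44156418 to 63294580 counts in control seeds at 14 DAP, from 43699121 to 46692149 at 18 DAP and from 46616460 to 51907421 at 20 DAP. In heat-grown seeds they ran from 43098313 to 50253849 at 14 DAP, from 43869724 to 50833877 at 18 DAP, from 48857924 to 58355063 in intact and from 41640918 to 45933487 in ruptured seeds at 20 DAP. Of 119367 gene records 93786 had a count and 61472 were tested, of which 410 carried a gene name, so named genes were a small part of every count of genes. Values are CPM, counts scaled to the TMM-adjusted library total, as mean ± SD, n = 4 per group, and p values are Benjamini-Hochberg adjusted edgeR values unless a test is named. The libraries came from seeds and not from separated tissues, so CPM is a share of the RNA of all seed tissues. A fall of coat genes cannot be told apart from a smaller share of coat tissue, which was not measured. Where a group had no count, a lower bound was computed from a floor of 3 counts per library, which covers counting error only. The comparisons, the gene lists, the naming rule and the alternatives were set before the data were examined, apart from those named as added.

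The groups separated along the first principal component, which held 54.4% of the variance, in the order of age within each temperature. Heat-grown seeds at 14 DAP lay nearer to control seeds at 20 DAP than to control seeds of their own age. Across genes, their mean log2 CPM correlated at r = 0.979 with control seeds at 20 DAP, 0.969 with control seeds at 18 DAP and 0.857 with control seeds at 14 DAP. Genes are not independent replicates, so these 3 values describe the libraries and carry no test. The 10 most counted genes took 2.65% ± 0.03 of all counts in control seeds at 20 DAP, 19.1% ± 0.35 in intact heat-grown seeds and 13.5% ± 0.53 in ruptured seeds. Replicate 1 of the heat-grown seeds at 14 DAP stood apart from its group: 815 of 37725 genes were over 4-fold below its 3 sisters, against at most 13 in any other library.

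**Figure D1:**
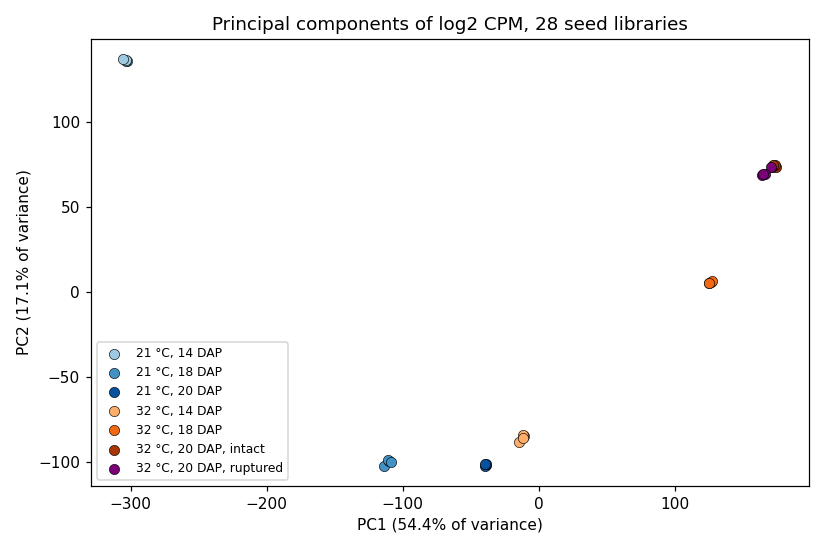
Principal components 1 and 2 of log2 CPM for the 28 libraries, coloured by group, with the percent of variance on each axis. Component 1 holds 54.4% and component 2 holds 17.1%; the 4 libraries of each group sit together.

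The first comparison asked what warm days changed in young seeds at 14 DAP. The fatty acid elongase gene FAE1 stood at 269.8 ± 39.3 CPM in the heat against 3.17 ± 0.34 (84.9-fold), the omega-3 desaturase gene FAD3 at 319 ± 74.8 against 12 ± 0.49 (26.4-fold), and the maturation regulator ABI3 at 64.4 ± 12.7 against 5.73 ± 0.14. The cellulose synthase genes of secondary walls rose too, CesA8 from 1.03 ± 0.21 to 157 ± 5.80 CPM (151-fold) and CesA4 (LOC106411008) from 0.40 ± 0.21 to 31.0 ± 2.94 (74.6-fold). TT16, a MADS-box factor of the endothelium, fell 12.4-fold (LOC106444269, 1.77 ± 0.80 against 21.8 ± 1.06) and 7.96-fold (LOC106359505). MYB61, a regulator of coat mucilage, fell 3.40-fold from 117 ± 4.56 to 34.5 ± 10.4.

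Of 12 measured oil genes, 11 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 9.62e-07). The one that fell was WRI1, a regulator of fatty acid synthesis (LOC106412050, log2 -0.46). The flavonoid and proanthocyanidin list fell (10 of 16 fell and 1 rose, adjusted over the list alone also 10 and 1; adjusted p = 0.000442), including the precursor transporter TT12 (LOC106356820, log2 -1.91). The gene that rose was TT10, a laccase-like oxidase of the seed coat (LOC106399890, log2 6.71). All 4 mucilage and seed coat regulators fell, adjusted over the list alone also 4 (adjusted p = 0.00788), with TTG2 (LOC106444738) down by a log2 change of -1.17. That list was not past the threshold at adjusted p = 0.122 with an estimated correlation. The 3 redox genes rose, adjusted over the list alone also 3 (adjusted p = 0.00374): the 1-Cys peroxiredoxin per1 went from 0.08 ± 0.06 to 19.3 ± 2.07 CPM (212-fold) and catalase from 22.1 ± 1.17 to 170.4 ± 19.7 (7.69-fold).

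The lignin and secondary wall list went both ways at 14 DAP, with 4 rises and 4 falls among 12 (6 and 4 adjusted over the list alone; adjusted p = 0.190): the CesA genes rose, while C4H and PAL1 (LOC106388514), at the entry to phenylpropanoids, fell (log2 -0.72 for C4H LOC106446415 and -1.16). Among maturation regulators 3 fell and 1 rose, adjusted over the list alone likewise (adjusted p = 0.395): ABI5 fell 8.74-fold, LEC1 1.44-fold (134 ± 4.68 against 193 ± 9.39 CPM) and NF-YB9 (LOC106425624) fell by 0.41 on the log2 scale. NF-YB9 is another name of LEC1, so LEC1 and NF-YB9 are here gene copies of the same regulator. Late embryogenesis genes gave 2 rises among 3 (2 rises and 1 fall adjusted over the list alone; adjusted p = 0.736). Abscisic acid signalling genes had 2 falls and 1 rise among 4, adjusted over the list alone likewise (adjusted p = 0.395), ABF3 down 1.56-fold and ABF4 down 1.17-fold. Outside the lists, the myrosinase gene Myr2.Bn1 had no count in control seeds and 27.8 ± 3.79 CPM in heat-grown seeds (at least 571-fold higher), and the sinapoyltransferase gene SCT1 (143-fold) and S4 (LOC106446163, 255-fold) rose. MyAP1, a myrosinase-associated protein, fell from 148 ± 6.49 to 0.15 ± 0.03 CPM (972-fold), and CYP83B1-5 of glucosinolate synthesis (18.2-fold), MYB12.1 (5.10-fold) and the MADS-box gene SHP2 (3.84-fold) fell. Across all genes 18034 rose and 15760 fell, of which 10165 and 6488 by at least 2-fold. The total of 33794 became 26696 when only the groups compared were fitted. For ABF4 (LOC106363379), heat effect at 14 DAP, adjusted p was 0.0082, and 0.0624 when only the groups of the comparison were fitted.

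At 18 DAP the cruciferin gene CRUA, a storage globulin, stood at 2209 ± 36.1 CPM in heat-grown seeds and had no count in control seeds (at least 37365-fold higher). The oil-body protein genes CLO1 rose from 0.18 ± 0.12 to 40.6 ± 3.23 CPM (LOC106429504, 226-fold) and from 3.41 ± 0.47 to 267 ± 12 (LOC106428308, 78.3-fold), and the dehydration-tolerance gene lea3-3 from 0.17 ± 0.10 to 5.46 ± 1.01 (31.2-fold). TT12 fell 5.21-fold (9.90 ± 1.2 against 51.7 ± 2.08 CPM) and MYB61 4.14-fold (16.4 ± 1.09 against 67.7 ± 1.68). The copies LEC1 and NF-YB9 of the same embryo regulator fell 2.67-fold and 2.57-fold. The cysteine protease gene CysP1, abundant in control seeds at 2105 ± 71 CPM, stood at 45.3 ± 1.12 (46.5-fold lower), and PCNA of DNA replication fell 3.97-fold.

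Oil genes rose as a list at 18 DAP (8 rose and 1 fell, adjusted over the list alone also 8 and 1; adjusted p = 8.26e-09), WRI1 (LOC106412050) falling again (log2 -0.46). Flavonoid genes fell (9 fell and 1 rose, 11 and 1 adjusted over the list alone; adjusted p = 0.000151), with TT16 (LOC106444269) down 5.60-fold and TT10 (LOC106399890) up by 0.81 on the log2 scale. All 4 mucilage regulators fell, adjusted over the list alone also 4 (adjusted p = 0.000583), TTG2 1.82-fold. Redox genes rose (2 rose and 1 fell, adjusted over the list alone likewise; adjusted p = 0.0126), per1 9.13-fold and catalase 3.33-fold, while the superoxide dismutase gene FeSOD fell (LOC106348338, log2 -0.57). The lignin and secondary wall list fell (6 fell and 2 rose, adjusted over the list alone likewise; adjusted p = 0.0400), including C4H (LOC106446415, 2.76-fold) and PAL1 (LOC106391500, 290.2 ± 16.3 to 119 ± 2.04 CPM, 2.45-fold). ABF4 (2.21-fold) and HAB1 (LOC106354239, 1.3-fold) rose, 2 of 4 abscisic acid signalling genes, adjusted over the list alone also 2 (adjusted p = 0.0736). Maturation regulators had 2 falls and 1 rise, adjusted over the list alone likewise (adjusted p = 0.105), the rise being ABI3 (LOC106418223, log2 1.22). In all 15002 genes rose and 14257 fell, 6464 and 5841 by at least 2-fold; Myr2.Bn1 (233-fold) and S4 (LOC106391034, 36-fold) were among the rises.

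The 3 late embryogenesis genes gave 2 rises at 18 DAP, adjusted over the list alone also 2 (gene list lea, heat effect at 18 DAP; adjusted p = 0.0509). This p moved past the threshold without TCT_18DAP replicate 1 (0.0482), THT_18DAP replicate 1 (0.0483), replicate 2 (0.0468), replicate 3 (0.0349) or replicate 4 (0.0469). It was 0.0397 with the replicate number as a block, and 0.0251 without THT_14DAP replicate 1 and THT_20DAP_SCR replicate 1, the pair of libraries in doubt. They were picked by their values on the third principal component, -207.6 (sisters -39.9 to -34.5) and -45.7 (sisters -17.7 to -7.79). Leaving out that pair, and leaving out single libraries for lists, were alternatives added after the data had been seen. In the 5 main comparisons every list call held with an estimated correlation between genes in place of the preset 0.01, except the 3 mucilage calls at 14 DAP, at 20 DAP and in ruptured against control seeds and the abscisic acid signalling call at 20 DAP.

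At 20 DAP intact heat-grown seeds held 13888 ± 255 CPM of CRUA against 6.68 ± 0.43 in control seeds (2079-fold). CLO1 stood 218-fold (LOC106429504) and 62.5-fold (LOC106428308) higher, at 149.9 ± 6.98 and 811 ± 34.3 CPM. The late embryogenesis genes lea3-1 (38.8-fold) and lea3-3 (36.9-fold) rose. LEC1 fell 4.19-fold (32.1 ± 1.86 against 135 ± 3.67 CPM) and NF-YB9 4.41-fold, PCNA fell 10.6-fold, and CysP1 fell 84.4-fold from 703 ± 5.39 to 8.33 ± 1.1 CPM. The coat genes MYB61 (3.65-fold), TT12 (3.46-fold) and TT16 (LOC106444269, 2.88-fold) were lower than in control seeds.

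As lists, oil genes rose at 20 DAP (8 rose and 1 fell, adjusted over the list alone likewise; adjusted p = 2.10e-08), and flavonoid genes fell (7 of 16, adjusted over the list alone also 7; adjusted p = 0.000913). The 4 mucilage regulators fell, adjusted over the list alone also 4 (adjusted p = 0.00228), NAC56 (LOC106402521) 1.86-fold; for these 4 genes adjusted p = 0.0650 with an estimated correlation. Redox genes rose (2 rose and 1 fell, adjusted over the list alone likewise; adjusted p = 0.0116), per1 10.9-fold and catalase 2.86-fold. Abscisic acid signalling genes rose as a list, 2 of 4, adjusted over the list alone also 2 (gene list aba_signalling, heat effect at 20 DAP, intact seeds, camera adjusted p = 0.0401). The genes that rose were ABF4 (2.86-fold) and HAB1 (LOC106354239, 1.43-fold), and the list test does not measure signalling itself. For this list the camera adjusted p was 0.0873 with an estimated correlation, 0.0569 without THT_20DAP_noSCR replicate 3 and 0.0581 without the pair of libraries in doubt. Lignin genes went both ways (4 rose and 6 fell, adjusted over the list alone likewise; adjusted p = 0.665): PAL1 (LOC106391500) fell 2.10-fold and CesA8 1.95-fold. Late embryogenesis genes (2 rose and 1 fell, adjusted over the list alone likewise; adjusted p = 0.0736) and maturation regulators (2 and 2, adjusted over the list alone likewise; adjusted p = 0.255) passed no list test. Across all genes 14655 rose and 15022 fell, 6127 and 6518 by at least 2-fold.

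Slo-A and SLO1 had no count in control seeds at 20 DAP and were at least 773-fold and 483-fold higher in intact heat-grown seeds (42.9 ± 1.24 and 26.8 ± 1.2 CPM), and GRF2b1 fell 4.41-fold. For bgl, at 91.9 ± 0.70 CPM in the heat, every control count came from TCT_20DAP replicate 2 (group mean 0.019 CPM). Its log2 change was 12.09, and 15.13 without that replicate, a value that depends on the prior count of the fit.

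**Figure D2:**
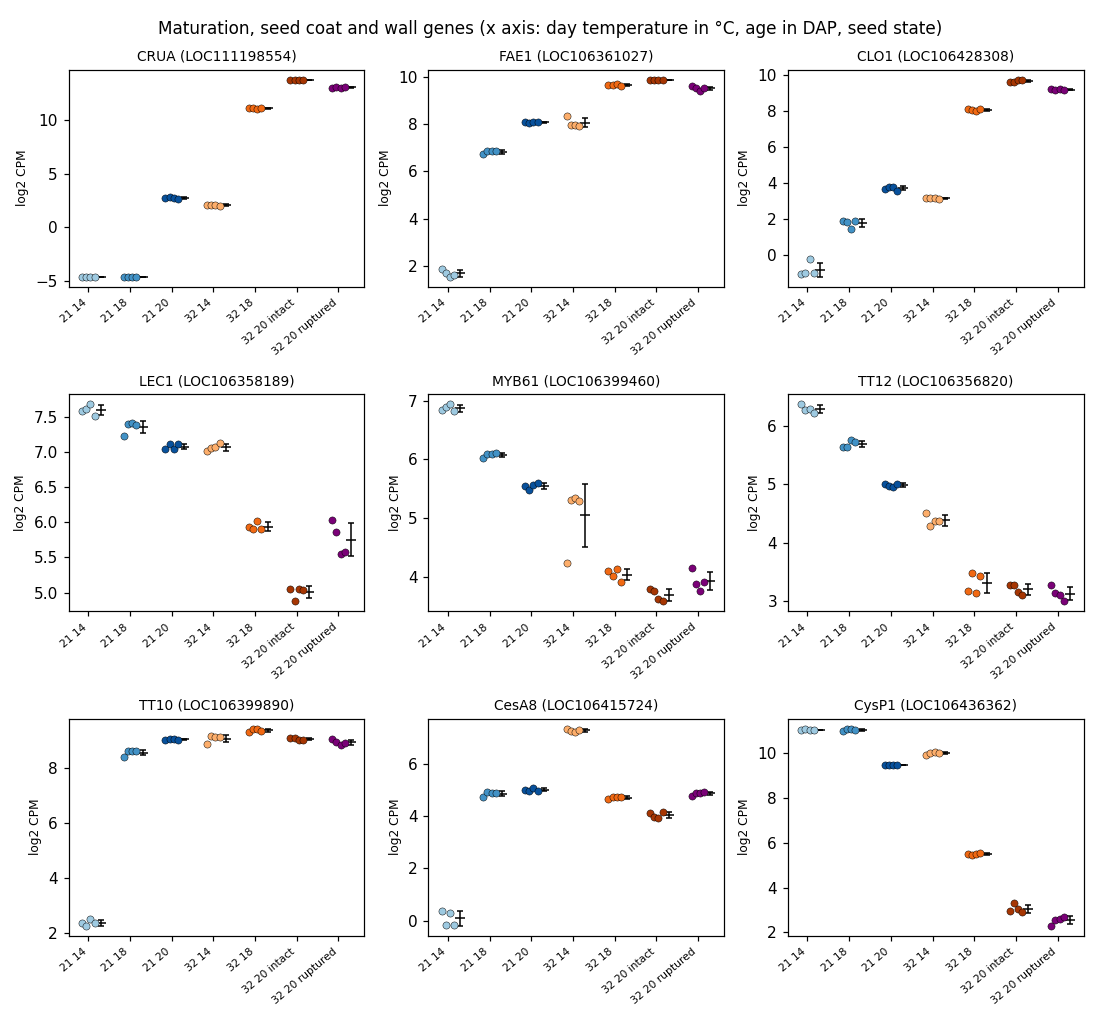
Log2 CPM of 9 named genes in each library (points), with group mean and SD (bars), by day temperature, age and seed state. CRUA reached 13888 CPM in intact heat-grown seeds at 20 DAP and had no count in control seeds at 14 and 18 DAP, while CysP1 stood at 2105 CPM in control seeds at 18 DAP and at 8.33 CPM in intact heat-grown seeds at 20 DAP.

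Ruptured heat-grown seeds were also compared with control seeds at 20 DAP. CRUA stood at 8564 ± 366 CPM (1282-fold), CLO1 at 82.2 ± 3.72 (LOC106429504, 119-fold) and 577 ± 17.2 (LOC106428308, 44.5-fold), lea3-1 34.7-fold and lea3-3 19.8-fold higher. CysP1 was 121-fold, PCNA 6.36-fold, GRF2b1 4.98-fold and the long-chain acyl-CoA synthetase gene LACS1 3.15-fold lower. Among coat genes TT12 fell 3.63-fold (LOC106356820) and 2.17-fold (LOC106428225), MYB61 3.08-fold and NAC56 (LOC106402521) 2.24-fold. LEC1 (2.48-fold) and NF-YB9 (2.64-fold) were lower, and ABF4 (2.28-fold), HAB1 (LOC106354239, 1.22-fold), per1 (10.9-fold) and catalase (1.96-fold) higher. C4H (LOC106446415, 2.66-fold) and PAL1 (LOC106391500, 2.44-fold) were lower.

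Oil genes rose in this comparison (8 rose and 1 fell, adjusted over the list alone likewise; adjusted p = 1.00e-06) and flavonoid genes fell (9 of 16, 10 adjusted over the list alone; adjusted p = 0.000144). The 4 mucilage regulators fell, adjusted over the list alone also 4 (adjusted p = 0.00142; adjusted p = 0.0720 with an estimated correlation). The redox list (gene list redox, ruptured heat-grown seeds against control seeds at 20 DAP; 2 rose and 1 fell, adjusted over the list alone likewise) had adjusted p = 0.0603, and passed without THT_20DAP_SCR replicate 1 (0.0397) or replicate 2 (0.0492) and without the pair of libraries in doubt (0.0264). The late embryogenesis list (2 rose, adjusted over the list alone also 2) had adjusted p = 0.0941, and 0.0437 without THT_20DAP_SCR replicate 1. Lignin (4 rose and 6 fell, adjusted over the list alone likewise; adjusted p = 0.633), maturation (2 and 2, adjusted over the list alone likewise; adjusted p = 0.325) and abscisic acid signalling genes (2 rose and 1 fell, 2 and 2 adjusted over the list alone; adjusted p = 0.405) passed no list test. In all 15725 genes rose and 15974 fell, 6851 and 6241 by at least 2-fold. Slo-A and SLO1, without a count in control seeds, were at least 779-fold and 345-fold higher. bgl stood at 42.7 ± 3.29 CPM, with a log2 change of 10.98 and of 14.03 without TCT_20DAP replicate 2, the only control library with a count.

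The last main comparison asked what set ruptured seeds apart from intact seeds of the same age and temperature. Lower in ruptured seeds were CRUA at 8564 ± 366 against 13888 ± 255 CPM (log2 -0.70), CLO1 at 82.2 ± 3.72 against 149.9 ± 6.98 (LOC106429504, 1.82-fold lower) and 329.9 ± 20.1 against 518 ± 19.3 (LOC106445076, 1.57-fold), and lea3-3 (1.86-fold). The copies LEC1 (54.4 ± 8.85 against 32.1 ± 1.86 CPM, 1.69-fold) and NF-YB9 (1.67-fold) of the same embryo regulator were higher, as was PCNA (log2 0.74). PGIP2, a polygalacturonase-inhibiting protein, rose 2.02-fold from 17.1 ± 1.3 to 34.6 ± 3.86 CPM, with the calcium-sensor kinase genes CIPK17.1 (1.84-fold) and CIPK9.1 (1.69-fold), CesA8 (16.5 ± 1.26 to 29.4 ± 1.29, 1.78-fold) and WRKY11 (1.72-fold). In all 5586 genes were higher and 5724 lower in ruptured seeds, but 1354 and 467 by at least 2-fold.

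Of the 12 oil genes 7 fell and none rose (8 and 0 adjusted over the list alone; camera adjusted p = 6.16e-10). Abscisic acid signalling genes fell (3 of 4, 4 adjusted over the list alone; adjusted p = 0.00372), ABF4 and ABF3 each 1.25-fold, and so did redox genes (2 of 3, adjusted over the list alone also 2; adjusted p = 0.0115), FeSOD 1.61-fold and catalase 1.46-fold. The maturation list (2 rose, the copies LEC1 and NF-YB9, adjusted over the list alone also 2) had adjusted p = 0.0523 (gene list maturation_regulator, ruptured against intact heat-grown seeds at 20 DAP). It passed without THT_20DAP_noSCR replicate 1 (0.0388) or replicate 3 (0.0347), and without THT_20DAP_SCR replicate 1 (0.0442), replicate 3 (0.0358) or replicate 4 (0.0368), and at 0.0441 without the pair of libraries in doubt.

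Seed coat lists passed no test between ruptured and intact seeds. Flavonoid genes (gene list flavonoid_pa, ruptured against intact heat-grown seeds at 20 DAP) had 2 falls and 1 rise (4 and 1 adjusted over the list alone; adjusted p = 0.122, and 0.0441 without the pair of libraries in doubt), with F3H 1.49-fold and CHSB1 1.15-fold lower and TT16 (LOC106444269) higher by 1.17 on the log2 scale. Mucilage regulators had 2 falls, adjusted over the list alone also 2 (adjusted p = 0.313), NAC56 at 1.33-fold (LOC106418539) and 1.2-fold (LOC106402521) lower. Lignin genes had 3 falls and 1 rise, adjusted over the list alone likewise (adjusted p = 0.451), C4H (LOC106446415) 2.34-fold and PAL1 (LOC106391500) 1.16-fold lower; lea genes had 1 fall, adjusted over the list alone also 1 (adjusted p = 0.157). Other falls were bgl (2.15-fold), S4 (LOC106352688, 2.13-fold) and IPS, a myo-inositol-phosphate synthase (1.86-fold). The call for NAC56 (LOC106402521), ruptured against intact heat-grown seeds at 20 DAP, had adjusted p = 0.0359 and was lost without THT_20DAP_noSCR replicate 2 (0.0553), replicate 3 (0.115) or replicate 4 (0.0719) and without THT_20DAP_SCR replicate 1 (0.173) or replicate 4 (0.0693), and without the pair of libraries in doubt (0.0610). The call for PAL1 (LOC106391500), ruptured against intact heat-grown seeds at 20 DAP, had adjusted p = 0.0400 and was lost without THT_20DAP_noSCR replicate 1 (0.128), replicate 2 (0.0573) or replicate 3 (0.0938), without THT_20DAP_SCR replicate 1 (0.108), replicate 2 (0.0868) or replicate 3 (0.0813), and with upper-quartile factors (0.0580).

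**Figure D3:**
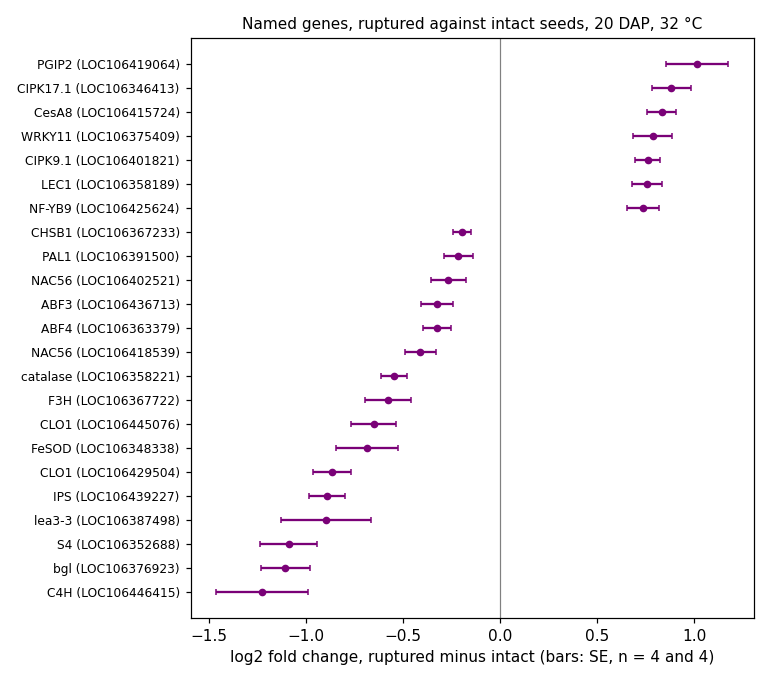
Log2 fold change with standard error of the 23 genes named for ruptured against intact heat-grown seeds at 20 DAP. PGIP2 was highest at 1.02 and C4H (LOC106446415) lowest at -1.23.

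Fixed lists with fewer than 3 tested genes were read gene by gene in the order heat at 14, 18 and 20 DAP, ruptured against control, and ruptured against intact. The cognate heat shock gene Hsc70 (LOC106361615) fell in the first 4 (log2 -0.58, -1.21, -1.07 and -1.03) and stood at 0.04 in the last, which was not past the threshold. The gene Expansin (LOC106391217) rose at 14 DAP (2.81) and fell at 18 and 20 DAP and in ruptured seeds (-0.34, -1.09 and -0.95). Of the cuticle acyltransferases, GPAT4 fell at 14 DAP (LOC106370865, -6.76; LOC106358370, -4.38) and rose in the next 3 comparisons, by 1.55, 1.94 and 2.80 and by 2.05, 2.85 and 3.53. RGA (LOC106445425), a repressor of gibberellin signalling, rose in the first 4 (0.83, 0.91, 0.72 and 0.53), and GA1 (LOC106368534) fell at 18 DAP (-0.33) and rose in ruptured against control seeds (0.35). In abscisic acid synthesis ZEP (LOC106358361) rose in the first 4 (0.28, 0.61, 0.67 and 0.38) and fell in the last (-0.29), while NCED3 (LOC106387066) fell at 14 and 18 DAP and in ruptured against control seeds (-0.37, -0.55 and -0.45). NAC92 (LOC106449568), a senescence regulator, rose at 14 DAP (1.24) and fell at 20 DAP (-1.14). The storage protein list (CRUA), reserve mobilisation list (CysP1) and cell cycle list (PCNA) held 1 tested gene each. At 14 DAP CRUA had no count in control seeds and 4.21 ± 0.14 CPM in the heat, CysP1 (LOC106436362) fell by 1.02 and PCNA (LOC106420145) by a log2 change of -0.19. Between ruptured and intact seeds CysP1 had a log2 change of -0.52. Photosynthesis, endosperm, chlorophyll breakdown and auxin lists had no named gene, and the 3 pectin genes were not tested.

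Normal development between 14 and 18 DAP was described in control seeds. TT10 rose 73.3-fold from 5.17 ± 0.39 to 379 ± 26.3 CPM, SCT1 61.6-fold and S4 (LOC106446163) 89.9-fold, while MyAP1 fell 706-fold, CYP83B1-5 13.9-fold and TT16 (LOC106444269) 5.17-fold. In all 14767 genes rose and 12920 fell. Between 18 and 20 DAP Myr2.Bn1 (17.5-fold), CLO1 (LOC106428308, 3.80-fold) and S4 (LOC106446163, 3.57-fold) rose and CysP1 (3.00-fold), MYB12.1 (1.67-fold) and TT12 (LOC106356820, 1.63-fold) fell, among 3477 rises and 2804 falls. The total of 6281 became 10997 when only the groups compared were fitted and 10899 without the 2 libraries in doubt (THT_14DAP replicate 1 and THT_20DAP_SCR replicate 1).

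In heat-grown seeds between 14 and 18 DAP, CRUA rose 525-fold from 4.21 ± 0.14 CPM, CLO1 (LOC106429504) 95.9-fold and S4 (LOC106391034) 11.8-fold. The secondary wall gene CesA7 fell 7.15-fold from 44 ± 4.43 CPM, and CysP1 fell 22.7-fold. For CesA4 (LOC106411008), development in heat, 18 against 14 DAP, the log2 change was -7.92, and -9.91 without THT_18DAP replicate 3. There were 9886 rises and 10498 falls, and the total of 20384 became 11994 when only the groups compared were fitted. Between 18 and 20 DAP, in intact seeds, SLO1 (12.9-fold), Slo-A (8.27-fold) and CRUA (6.29-fold) rose, and CysP1 (5.44-fold), PCNA (2.88-fold) and NF-YB9 (2.01-fold) fell. These were among 4017 rises and 5425 falls, a total of 9442 that became 14309 with only the groups compared and 14861 without the 2 libraries in doubt, THT_14DAP replicate 1 and THT_20DAP_SCR replicate 1.

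The heat effect, the difference between heat-grown and control seeds of the same age, changed with age. Development in either group can give such a change, and a shift in timing was not told apart from it. Between 14 and 18 DAP the heat effect became higher for CLO1 (LOC106428308, log2 2.28) and for the phospholipase gene PLD2 (1.97), and lower for CesA8 (-7.40) and TT10 (-5.90). At 18 DAP CesA8 stood at 26.2 ± 0.84 CPM in heat-grown and 29.3 ± 1.85 CPM in control seeds, and TT10 at 667 ± 27.5 and 379 ± 26.3 CPM. MyAP1 differed by 10.37 (9.43 without THT_18DAP replicate 4) and CesA4 (LOC106411008) by -9.55 (-11.54 without THT_18DAP replicate 3), in a contrast with 8738 higher and 12858 lower genes. At 18 DAP MyAP1 (LOC106348442) stood at 0.28 ± 0.28 CPM in heat-grown and 0.21 ± 0.04 CPM in control seeds, and CesA4 (LOC106411008) at 0.13 ± 0.20 and 1.29 ± 0.09 CPM. Between 18 and 20 DAP the heat effect became higher for BNF5H2, a ferulate 5-hydroxylase (1.37), PAL1 (LOC106388514, 1.08) and CIPK14.1 (1.05), and lower for Myr2.Bn1 (-4.32), GRF2b1 (-1.71) and CRUA (-8.70, which depends on the prior count because control seeds at 18 DAP had no count). Of these genes 2543 were higher and 4822 lower, a total of 7365 that became 12300 with only the groups compared and 12529 without THT_14DAP replicate 1 and THT_20DAP_SCR replicate 1. At all 3 ages 6380 genes rose and 5188 fell in the heat, where independent lists would share 1049 and 893, and 6894 genes were called in opposite directions in a pair of ages. The 3 comparisons came from 1 fit with the same spread per gene, so some genes are called more readily at every age. How much of the excess this gives was not tested, and the excess does not by itself measure a common heat response.

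To place heat-grown seeds on the course of normal development, genes were taken from control comparisons that shared no library with the heat comparison. At 14 DAP 87.5% of the genes that changed in control seeds between 18 and 20 DAP differed in the same direction in the heat. The mean log2 CPM of the risen minus the fallen genes was 0.33 ± 0.02 in heat-grown and -2.93 ± 0.01 in control seeds at 14 DAP, beside 0.43 ± 0.01 in control seeds at 20 DAP. At 18 DAP, on genes changed between 14 and 20 DAP, the position was 1.04 ± 0.01 against 0.20 ± 0.01, with 65.3% of genes in the same direction. At 20 DAP, on genes changed between 14 and 18 DAP, it was 0.82 ± 0.01 in intact heat-grown and 0.86 ± 0.003 in control seeds, with 46.7% in the same direction. This small difference of -0.0465 turned to 0.16 with genes changed at least 2-fold. It was -0.0280, -0.0342, -0.0333 and -0.0310 without TCT_18DAP replicate 1, 2, 3 and 4. With genes changed at least 2-fold the differences at 14 and 18 DAP, 3.26 and 0.84, became 5.97 and 1.41. Ruptured seeds lay at 0.88 ± 0.01 and intact seeds at 0.94 ± 0.004 on genes changed between 14 and 20 DAP, with 44.8% in the same direction. Each of the 4 differences was larger than the spread between replicates, with no overlap of the 8 libraries, and had p = 0.0286 in a two-sided exact permutation test, the smallest value that 4 against 4 libraries can give. On genes changed between 14 and 20 DAP, heat-grown seeds stood at 1.04 at 18 DAP and intact ones at 0.94 at 20 DAP. Control seeds at 20 DAP lay at 0.74. The heat-grown values were 0.98 and 0.82 on genes changed between 14 and 18 DAP, but 1.98 and 2.27 on those changed between 18 and 20 DAP. On genes from comparisons with 14 DAP the position thus did not rise with age in older heat-grown seeds, and does not measure their stage.

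**Figure D4:**
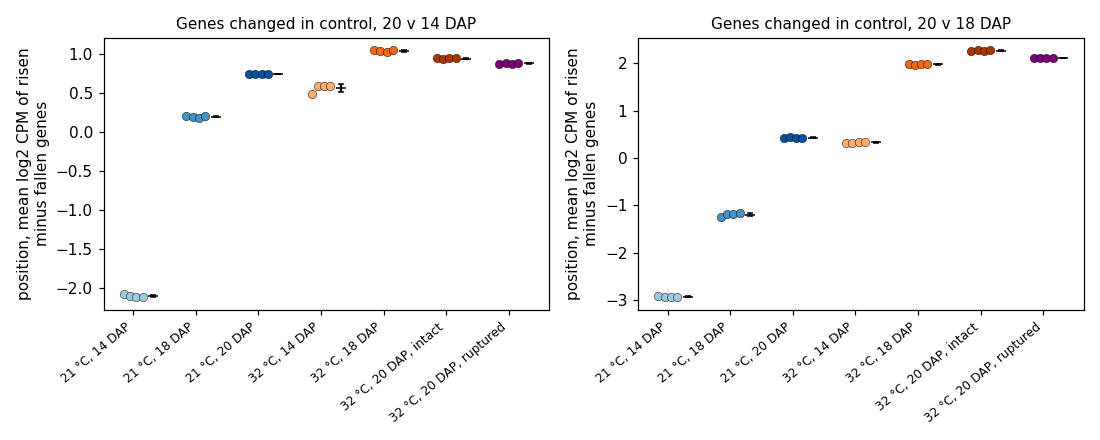
Position of each library (points, with group mean and SD) on the genes changed in control seeds between 14 and 20 DAP (left) and between 18 and 20 DAP (right), as mean log2 CPM of risen minus fallen genes. On the right, heat-grown seeds at 14 DAP lie at 0.33 and control seeds at 14 DAP at -2.93.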

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

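The 3 tests on the heat-grown library at 14 DAP, the tests of abundant genes and of depth on positions at 18 DAP, the comparison of heat-grown seeds at 14 DAP with control seeds at 20 DAP, the fits without a pair of libraries in doubt, THT_14DAP replicate 1 and THT_20DAP_SCR replicate 1, and the requirement placed on the timing test were chosen after the results had been seen.

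In 29 of 241 groups of 4 libraries 1 library lay far from the other 3, where chance alone gives about 1 in 20, or 12.05. Of these, 10 fell on THT_14DAP replicate 1. Its log2 CPM was higher than in its sisters for SCT1 (6.68, others 5.98 to 6.08), FAE1 (8.36, others 7.95 to 7.99) and FAD3 (8.75, others 8.11 to 8.15). It was lower for SHP2 (5.50, others 6.39 to 6.52), MYB61 (4.24, others 5.29 to 5.34), CLO1 (LOC106429504; -1.40, others -1.05 to -1.01), BiP (5.57, others 6.42 to 6.47) and PAL1 (LOC106388514; 3.83, others 4.71 to 4.74). Its position was also lower on the genes changed in control seeds between 14 and 20 DAP (0.49, others 0.59) and between 14 and 18 DAP (0.62, others 0.73 to 0.74).

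Over 4-fold below its sisters were 815 of 37725 genes in THT_14DAP replicate 1, with 12 above. Its total was 0.998 of the mean of its sisters, which argues against a lower depth. The lower genes made up 8.33% of 3242 genes with 1 exon and 0.701% of 16700 genes with 8 or more exons, a ratio of 11.9, so a library bias that follows gene structure may account for them. Loss of a seed tissue with its own transcripts stays open, because the lower genes varied between the other groups 1.28 times as much as genes of like abundance, with random draws of genes from 1.13 to 1.44. Without this library 35251 genes were called for heat at 14 DAP, beside 33794 with it.

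THT_20DAP_SCR replicate 1 stood apart in none of the 241 groups and was doubted for its value on the third principal component alone (-45.7, sisters -17.7 to -7.79). TCT_18DAP replicate 1, also apart there (47.8, sisters 29.3 to 32.7), was not in the pair left out. For TCT_18DAP replicate 1, which stood apart 5 times, log2 CPM was lower for LEC1 (7.23, others 7.39 to 7.41), catalase (7.32, others 7.47 to 7.49), TT10 (8.41, others 8.61 to 8.63) and SCT1 (4.67, others 5.07 to 5.13), and 67427 genes were detected against 69282 to 69290. TCT_20DAP replicate 4 was lower for CLO1 (LOC106429504; -1.02, others -0.35 to -0.26), LACS1 (4.82, others 5.05 to 5.07) and TT12 (LOC106428225; 5.97, others 6.05 to 6.06) and higher for PCNA (6.79, others 6.73 to 6.74). TCT_20DAP replicate 2 was higher for bgl (-3.09, others -4.62) and lea3-1 (-2.10, others -3.18 to -3.08) and lower for HAB1 (5.07, others 5.22 to 5.24). TCT_14DAP replicate 4 was lower for per1 (-4.62, others -2.88 to -2.60) and higher for MYB12.1 (4.57, others 4.23 to 4.29). In THT_20DAP_noSCR replicate 2 LEC1 (4.88, others 5.05) and the position on genes changed between 14 and 20 DAP (0.93, others 0.94) were lower. The remaining values were CLO1 (LOC106428308) in TCT_18DAP replicate 3 (1.46, others 1.85 to 1.91), HAB1 in THT_18DAP replicate 4 (5.59, others 5.43 to 5.45) and C4H (LOC106446415) in THT_20DAP_SCR replicate 2 (-0.44, others 0.47 to 0.61).

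The heat effect differed between ages by a test of the difference itself, which does not tell a changed heat response apart from a shift in timing. Between 14 and 18 DAP 21596 genes differed, among them MyAP1 (log2 10.37, and 9.43 without THT_18DAP replicate 4), CLO1 (LOC106428308, 2.28), PLD2 (1.97), CesA4 (-9.55, and -11.54 without THT_18DAP replicate 3), CesA8 (-7.40) and TT10 (-5.90). Between 18 and 20 DAP 7365 genes differed, among them BNF5H2 (1.37), PAL1 (LOC106388514, 1.08), CIPK14.1 (1.05), CRUA (-8.70, which depends on the prior count), Myr2.Bn1 (-4.32) and GRF2b1 (-1.71).

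At 18 DAP the position of heat-grown seeds on genes changed in control seeds between 14 and 20 DAP was 0.84 above that of control seeds. It does not measure the stage of older heat-grown seeds, which stood at 1.04 at 18 DAP and, intact, at 0.94 at 20 DAP. A scaling shift from a few abundant genes would move genes that rose and genes that fell in control development alike, but in the heat the mean log2 CPM was 0.457 higher for the first and changed by -0.384 for the second, with no overlap of libraries and the same directions with RLE or upper-quartile factors, which argues against it. Depth is argued against by a difference of 0.843 between the 2 heat-grown and 3 control libraries whose totals lay in the range that both groups covered. For earlier timing of development as the whole account of the heat effect, heat-grown seeds at 14 DAP differed from control seeds at 20 DAP in 14883 genes, 2.37 times the 6281 that separated control seeds at 20 and 18 DAP, which passed a bound of 1.5 written when the likeness of the groups and the number 6281 had been seen but not the genes of this comparison. That bound was a poor one. The ratio was 0.613 when only the groups of each comparison were fitted, and 1.48 without THT_14DAP replicate 1 and THT_20DAP_SCR replicate 1. A ratio above it in all 3 fits was then required, so the ratio leaves open timing as the whole account and a heat effect of its own. With an estimated correlation the lignin (camera adjusted p = 0.0134), flavonoid (0.0438) and redox lists (0.0438) differed from control seeds at 20 DAP, and no other fixed list passed. Likeness to that age was thus not complete. By position these seeds (0.33) lay between control seeds at 18 (-1.20) and 20 DAP (0.43), a stage that was not sampled.

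Ruptured and intact heat-grown seeds differed in 11310 genes. Without THT_20DAP_SCR replicate 1 the number was 8233, and with the 100 most counted genes left out 11259, which argues against that library and against a few abundant genes as the cause. A difference in developmental stage may contribute and stays open: of 7385 genes called in both, 42.6% moved along the change of control seeds from 14 to 20 DAP, a share between the limits set in advance. Along the change of heat-grown seeds from 14 to 18 DAP 22.8% of 5962 genes did, below the lower limit set for the control change. Most of these genes moved against that change, as a less advanced stage of ruptured seeds would give. No limit had been set in advance for the heat change, whose 14 DAP group includes THT_14DAP replicate 1. On the third principal component, where that library stood apart (-207.6), ruptured libraries (-45.7 to -7.79) lay on its side of intact ones (28.2 to 33.6). A library bias was not tested in ruptured seeds, so this share does not tell it apart from stage. Rupture of the coat itself, the difference that the design names, stays open as untested.

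Of the 35 splits of the 8 libraries only 1, the real one, called as many genes in each comparison of 2 groups. That is the smallest share such splits can give, and it was not adjusted for the number of comparisons. It argues against chance assignment of libraries to groups if the 4 libraries of a group are independent, which the labels do not settle. Every other split put libraries of both real groups on each side, so its few calls are no rate of false calls. Fitted on the groups compared, the real split called 26696 genes for heat at 14 DAP, 30939 at 18 DAP and 33714 at 20 DAP, and no other split more than 1. It called 33246 for ruptured against control (highest other 1), 14699 for ruptured against intact (2), 30971 for control seeds from 14 to 18 DAP (0), 10997 from 18 to 20 DAP (1), 11994 for heat-grown seeds from 14 to 18 DAP (1), 14309 from 18 to 20 DAP (2) and 6738 for heat-grown seeds at 14 DAP against control seeds at 20 DAP (2). For the differences in heat effect, 1 of 25 splits, the real one, called as many genes, 19229 between 14 and 18 DAP (highest other 0) and 12300 between 18 and 20 DAP (0).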

How the results depend on the processing

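Leaving out the pair of libraries in doubt (THT_14DAP replicate 1 and THT_20DAP_SCR replicate 1), leaving out single libraries for lists and shared genes, and the comparison of heat-grown seeds at 14 DAP with control seeds at 20 DAP were chosen after the data had been seen. For 153 gene results and 2837 values under alternatives, 2823 kept direction and side of the threshold, 14 of 3 genes lost the threshold and 0 reversed. Most of these genes had been picked from the same data as the largest called changes without overlap. Their stability was thus largely given by that choice and does not carry over to other called genes. CRUA and CysP1 are among the 100 most counted genes and have no value where those were left out. Counts of called genes kept within 1.5 times in 224 cases and shared genes in 27. Lists kept the side of the threshold in 456 cases, where a change of direction was counted only if either adjusted p was below 0.05. Positions kept direction and side of the threshold in 79 cases. With genes past a log2 change of 1, though, the differences of 3.26 and 0.84 at 14 and 18 DAP became 5.97 and 1.41. At 20 DAP, -0.0465 became -0.0280, -0.0342, -0.0333 and -0.0310 without TCT_18DAP replicate 1, 2, 3 and 4. By construction, a log2 change of at least 1 lowered the counts to 16653, 12305 and 12645 for heat at 14, 18 and 20 DAP, 13092 for ruptured against control, 1821 for ruptured against intact, 12586 and 1713 for development in control seeds, 6697 and 2692 in heat-grown seeds, 11966 and 2795 for the differences in heat effect, 2718 for the added comparison and 3907 for shared genes. Fitting only the groups compared gave 10997 for control seeds from 18 to 20 DAP, 11994 and 14309 for heat-grown seeds from 14 to 18 and 18 to 20 DAP, 12300 for the later difference in heat effect and 6738 for the added comparison. Every comparison with heat-grown seeds at 14 DAP called fewer genes in this fit, and every other comparison more. For heat, 33794, 29259 and 29677 genes at 14, 18 and 20 DAP became 26696, 30939 and 33714, so their order depends on the fit. The main fit shares its spread over all groups, THT_14DAP replicate 1 included. Without the pair of libraries the numbers were 10899 for control seeds, 14861 for heat-grown seeds from 18 to 20 DAP and 12529 for the later difference, near those of that fit. The part of each library was not tested. Without that pair adjusted p was 0.0581 for gene list aba_signalling, heat effect at 20 DAP, intact seeds, 0.0251 for gene list lea, heat effect at 18 DAP, and 0.0264 for gene list redox, ruptured heat-grown seeds against control seeds at 20 DAP. It was 0.0441 for gene list flavonoid_pa, ruptured against intact heat-grown seeds at 20 DAP, and 0.0441 for the maturation list. With an estimated correlation it was 0.0873 for abscisic acid signalling at 20 DAP and 0.122, 0.0650 and 0.0720 for mucilage genes at 14 DAP, 20 DAP and in ruptured seeds. The cause of these changes was not tested. Leaving out each library moved adjusted p over 0.0293 to 0.0569 for abscisic acid signalling at 20 DAP, 0.0349 to 0.0699 for late embryogenesis genes at 18 DAP and 0.0437 to 0.105 in ruptured against control seeds, 0.0347 to 0.0863 for maturation genes in ruptured against intact seeds and 0.0397 to 0.0609 for redox genes in ruptured against control seeds. The position of heat-grown against control seeds at 20 DAP reversed to 0.16 with genes past a log2 change of 1; the cause was not tested. Depth limits genes with no count in a group to a lower bound of their fold.

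Averaged over all groups, samples with the same replicate number did not deviate together, so a block for the number removes no known source of variation. The average does not exclude pairing between particular groups, such as ruptured and intact seeds. With this block 33408, 28892 and 29393 genes were called for heat at 14, 18 and 20 DAP, 31360 for ruptured against control and 10851 for ruptured against intact seeds. Late embryogenesis genes at 18 DAP then had adjusted p = 0.0397; the cause was not tested.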

Other observations

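The 12 gene families and the comparison of heat-grown seeds at 14 DAP with control seeds at 20 DAP were chosen after the data had been seen, as were the fits that leave out libraries for lists. Genes of fatty acid synthesis in the plastid rose with heat at 14 DAP: 7 of 8 rose and 1 fell, adjusted over the list alone likewise (adjusted p = 0.000539, and adjusted p = 0.0134 with an estimated correlation). Examples were the carboxylase genes accA1 (LOC106427748, log2 1.77) and BnaC.BC.a (LOC106350529, 1.78) and the reductase gene enrB1 (LOC106439777, 1.61), while the thioesterase gene FatB (LOC106346329) fell by 0.61 on the log2 scale. At 20 DAP 1 rose and 6 fell (2 and 6 adjusted over the list alone; adjusted p = 0.154), and in ruptured against control seeds 5 fell (6 adjusted over the list alone; adjusted p = 0.00810, and adjusted p = 0.0585 with an estimated correlation). MADS-box genes of ovule and seed coat fell at 14 DAP (5 of 6, 5 and 1 rise adjusted over the list alone; adjusted p = 0.00105, and adjusted p = 0.0967 with an estimated correlation), among them SHP1b (LOC106428192, log2 -1.06) and 3 TT16 genes, which the flavonoid list holds too. At 18 DAP (added family ovule_mads, heat effect at 18 DAP) 5 fell, adjusted over the list alone also 5 (adjusted p = 0.0487, and adjusted p = 0.702 with an estimated correlation). That call was lost without TCT_18DAP replicate 2 (0.0543) or replicate 3 (0.0561), without THT_18DAP replicate 1 (0.0627), replicate 3 (0.0534) or replicate 4 (0.0895) and with RLE factors (0.0506). The cellulose synthase genes of primary walls fell at 14 DAP, 5 of 5, adjusted over the list alone also 5 (adjusted p = 0.00830, and adjusted p = 0.246 with an estimated correlation), led by CesA2.1 (LOC106348176, log2 -0.76).

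Between ruptured and intact heat-grown seeds 10 of 23 WRKY genes rose and 0 fell, adjusted over the list alone likewise (adjusted p = 0.00143, and adjusted p = 0.241 with an estimated correlation). WRKY26-1 (LOC106422600, log2 2.43), WRKY40-1 (LOC106430771, 2.39) and WRKY26.1 (LOC106397513, 1.79) rose most. Boron transporter genes (added family boron_transporter, ruptured against intact heat-grown seeds at 20 DAP) rose, 3 of 6, or 5 adjusted over the list alone (adjusted p = 0.0308, and adjusted p = 0.241 with an estimated correlation), and the call was lost without THT_20DAP_noSCR replicate 3 (0.0531) or replicate 4 (0.0653) or THT_20DAP_SCR replicate 4 (0.0577). NAC genes (added family nac, ruptured heat-grown seeds against control seeds at 20 DAP) rose, 16 of 30 with 3 falls (18 and 4 adjusted over the list alone; adjusted p = 0.0345, and adjusted p = 0.140 with an estimated correlation). That call was lost without TCT_20DAP replicate 2 (0.0510), without THT_20DAP_SCR replicate 4 (0.0503) and without the pair of libraries in doubt (0.0886). Calcium-sensor kinase genes (added family cipk_cbl, heat effect at 14 DAP) rose, 13 of 24 with 5 falls (14 and 5 adjusted over the list alone; adjusted p = 0.0492, and adjusted p = 0.135 with an estimated correlation). That call was lost without THT_14DAP replicate 2 (0.0505), replicate 3 (0.0716) or replicate 4 (0.0634) and with RLE factors (0.0523). Glucosinolate and myrosinase genes (added family glucosinolate_myrosinase, heat effect at 14 DAP) had 2 rises and 4 falls, adjusted over the list alone likewise (adjusted p = 0.0625), and passed without TCT_14DAP replicate 1 (0.0441), replicate 2 (0.0407), replicate 3 (0.0417) or replicate 4 (0.0424). MAP kinase cascade, calcium-dependent kinase, MYB and carotenoid genes passed no list test in the 5 main and the added comparison, with smallest adjusted p of 0.164, 0.123, 0.369 and 0.0934.

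Heat-grown seeds at 14 DAP, whose profile was closest to that of control seeds at 20 DAP, were compared with them directly. The secondary wall genes CesA4 (LOC106411008, 31.0 ± 2.94 against 0.48 ± 0.25 CPM, n = 4, 64.1-fold) and CesA7 (7.67-fold) and the galactinol synthase gene GolS-1 (LOC106392335, 17.7 ± 1.17 against 3.53 ± 0.47 CPM, 5.00-fold) were higher. BiP, a chaperone of the endoplasmic reticulum (77.2 ± 19.9 against 133 ± 4.87 CPM, 1.72-fold), PAL1 (LOC106388514, 1.69-fold) and S4 (LOC106352688, 1.67-fold) were lower. Lignin and secondary wall genes rose as a list (7 rose and 4 fell, adjusted over the list alone likewise; adjusted p = 0.00252). Flavonoid genes fell (6 fell and 1 rose, 8 and 2 adjusted over the list alone; adjusted p = 0.00211), as did redox genes (2 of 3, adjusted over the list alone also 2; adjusted p = 0.0101) and mucilage genes (3 of 4, adjusted over the list alone also 3; adjusted p = 0.0208, and adjusted p = 0.124 with an estimated correlation). The lignin, flavonoid and redox calls held with an estimated correlation (adjusted p = 0.0134, 0.0438 and 0.0438). Oil genes had 5 falls (5 and 1 rise adjusted over the list alone; adjusted p = 0.0828, and 0.0396 without THT_14DAP replicate 1). Abscisic acid signalling genes had 1 rise (2 adjusted over the list alone; adjusted p = 0.0643, and 0.0416 without TCT_20DAP replicate 1), late embryogenesis genes had no call (adjusted p = 0.771) and maturation regulators 1 fall, adjusted over the list alone also 1 (adjusted p = 0.208). Fatty acid synthesis genes (added family fatty_acid_synthesis, heat-grown seeds at 14 DAP against control seeds at 20 DAP) fell, 4 of 8, or 5 adjusted over the list alone (adjusted p = 0.0271, and adjusted p = 0.122 with an estimated correlation). That call was lost without THT_14DAP replicate 2 (0.0964), replicate 3 (0.0844) or replicate 4 (0.146), and adjusted p was 5.00e-06 without THT_14DAP replicate 1. Cellulose synthase genes of primary walls (added family primary_cellulose, heat-grown seeds at 14 DAP against control seeds at 20 DAP) had 1 rise and 2 falls, adjusted over the list alone likewise (adjusted p = 0.547), and passed at 0.00494 without THT_14DAP replicate 1. Across all genes 8147 were higher and 6736 lower, of which 1685 and 1033 by at least 2-fold, and the total of 14883 became 6738 when only the groups compared were fitted.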
